A study of Mus musculus with 9 samples.

How the data were processed

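RNA was sequenced from cultured mouse valvular interstitial cells of the aortic and mitral valves (C57BL/6J), 3 samples each given buffer (Control), LDL or oxLDL. Per the labels' protocols the cells grew in DMEM with 10% serum, added growth factors (basic FGF at 0.5 and EGF at 2 ng/mL) and insulin at 5 ug/mL, and were treated with 50 ug/mL lipoprotein or buffer for 24 h at 37 C and 5% CO2. The Control samples are called untreated in one label and given buffer in the treatment protocol. Libraries were made from amplified cDNA of 50 ng total RNA with a kit that does not mark strand, and read in 100 bp pairs. Reads of a gene and of a gene overlapping it on the other strand can therefore not be told apart, and near-identical copies may share reads.

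The authors deposited TPM values, a share of transcripts per library corrected for gene length. The submitters' processing notes name STAR, without a version, RSEM 1.3.1 and the genome build mm10, and the annotation is not given in the sources used here. The columns were TPM as deposited, summing to 999998.81 to 1000000.43, with 51810 genes in each of the 9 columns and 0 columns left out. TPM keeps no depth, so the reads per library are unknown, and no counting interval or detection limit is given. A gene listed at 0 may be a failed estimate.

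Choices of test, samples, gene lists and genes to name were made before the data were examined. Values were analysed as log2(TPM + 1), with a pseudocount of 1, for the 13495 genes with a mean of at least 1 TPM over the 9 libraries, leaving out 38315. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-dependent prior), two-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p under 0.05 as the threshold. All 9 libraries shared one estimate of the spread, with 6 residual degrees of freedom. Every adjusted p of a gene is limma's. A permutation of 3 against 3 samples cannot give a p below 0.1, so none was run per gene. Groups were called separated where all 3 samples of one treatment lay above all 3 of the other. Such genes made up 10.7, 7.33 and 8.31% of those tested in the LDL against Control, oxLDL against Control and oxLDL against LDL comparisons. Chance gives 10% if the libraries are independent. Libraries with the same replicate number deviated together, as given below, so shares under 10% do not show a lack of effect.

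Of 29 gene lists fixed beforehand, 27 were tested, with at least 3 tested members each. The cardiomyocyte list had 1 tested member and the haemoglobin and erythroid list 0. The sterol lists share 1 gene, and Cd36 is in the PPAR and scavenger lists. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with the other genes, adjusted over the 27 lists. It called 8, 11 and 10 lists in the 3 comparisons in the same order. With a correlation estimated per list, the calls that held were the PPAR and fatty acid oxidation list for LDL against Control and for oxLDL against LDL. The test fry was run beside it. Its PValue asks whether a list's genes move, on balance, one way, and its PValue.Mixed whether they change in either direction, and neither compares the list with other genes. They called 4, 1 and 1 lists, and 8, 5 and 2 lists, in the same order. The PValue called the cholesterol synthesis, sterol sensing, PPAR and NRF2 lists for LDL against Control, the p53 list for oxLDL against Control and the PPAR list for oxLDL against LDL. The same tests called, with the block, 4, 1 and 1, and 17, 9 and 7 lists. Member counts are given over all genes tested and adjusted over the list alone.

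Replicate numbers come from the sample titles. Deviations from the group means correlated at 0.172 to 0.497 in the 9 pairs of libraries with the same number, and at -0.309 to 0.13 in the 18 pairs with different numbers. The numbers therefore pair the samples, as shown by this check and not by a stated shared culture or day. The fit without the number remains the main one because it was fixed beforehand, and values with the number as a block (4 residual degrees of freedom) are printed beside a call over all genes or by camera that they change and beside a printed count of calls that they move by over 1.5 times.

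Genes were named by a rule. It took the 10 largest rises and 10 largest falls among called genes with separated groups, up to 4 called members per list or up to 2 that did not pass, and 11 genes in every comparison whatever their result, among them Abca1, Cd36, Pparg, Plin2, Hmox1, Acta2, Runx2, Il6 and Ccl2. Some genes that this rule selects are not reported here. Clone-named models and pseudogenes were counted but not named, members of lists that are only counted were left out, and genes named outside the rule are said to be chosen after their values were seen.

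Gene positions and lengths came from GENCODE M21 (GRCm38), which holds 47624 of the 51810 symbols (91.9%), 101 of them at more than 1 locus. AC165157.5 was not matched there, so no position is given for it. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

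The procedure was tested on simulated data with the measured gene means, replicate shifts and residual spread and 200 changed genes, in 10 runs over 13495 genes. For LDL against Control it recovered 94.6% of 4-fold and 80.1% of 2-fold changes with 2.4 false calls per run, and with the block 96% and 86.8% with 10.7 false calls. For oxLDL against LDL the shares were 94.2% and 79.8% with 1.5 false calls, and with the block 95.9% and 87.2% with 11.2. For oxLDL against Control, simulated without changes, it called 0 genes with and without the block. A random list of 20 unchanged genes had an unadjusted camera p under 0.05 in 0 to 2 of 10 runs. Residuals were drawn independently for each gene, so this does not show how often camera calls lists of correlated genes. Alternatives covered the pseudocount, the filter, the libraries in the fit, the prior, sample weights, scaling, the genes included, the block, the list test and each library left out.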

Results

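Transcript levels were measured by RNA sequencing in cultured mouse valvular interstitial cells (VICs), the fibroblast-like cells that populate the heart valve leaflets. The cells came from the aortic and mitral valves of C57BL/6J mice. They received buffer (Control), low-density lipoprotein (LDL, the main cholesterol carrier of human plasma) or its oxidised form (oxLDL), both at 50 ug/mL, for 24 h. Each treatment had 3 samples, and the values were TPM (each gene's length-corrected share of all transcripts in a library, scaled to a fixed total) for 51810 genes. Between 20985 and 21433 genes were listed above 0 in a library. The number of reads per library is unknown here, because TPM keeps no depth. Means are given ± SD over n = 3 libraries throughout, and log2 changes are on the scale of log2(TPM + 1), which understates the change of low genes. Nothing in the labels says that the 3 samples of a treatment were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

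The comparison of LDL with Control asked how VICs respond to the native lipoprotein. Of 20 genes of cholesterol synthesis 11 fell with LDL, and of 22 PPAR target and fatty acid oxidation genes 7 rose. Sqle, which opens the sterol branch by oxidising squalene, averaged 16.1 ± 1.08 TPM (SD, n = 3) with LDL and 43.7 ± 7.95 TPM (SD, n = 3) in Control, a 2.71-fold lower level. Pdk4, a kinase that restrains glucose oxidation, averaged 27.6 ± 1.53 TPM (SD, n = 3) against 8.72 ± 1 TPM (SD, n = 3), a 3.17-fold higher level. Of 13495 genes tested, 24 rose and 21 fell, and 3 of these 45 were clone-named or pseudogene models that are counted but not named.

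All 20 measured genes of cholesterol synthesis had lower means with LDL than in Control, with a median log2 change of -1. Of these, 11 fell over all genes tested, 19 fell adjusted over the list alone, and 18 fell over all genes with the replicate number as a block. Idi1, an isomerase of the isoprenoid steps, changed by -1.84 (95% CI -2.36 to -1.32, adjusted p = 0.02), and Fdps, which makes farnesyl diphosphate, by -1.72. Msmo1, Cyp51 and Nsdhl, enzymes of sterol demethylation, changed by -1.66, -1.51 and -1.04. Sqle changed by -1.37 (adjusted p = 0.01) and Hmgcs1, an early enzyme of the pathway, by -1.36. The list passed the set test with the preset correlation (adjusted p = 1.15e-40) but not with one estimated from the data (adjusted p = 0.0884 with an estimated correlation).

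Of the 13 measured genes of the sterol sensing list, 4 fell, 5 fell adjusted over the list alone, and 5 with the block. Insig1, which retains sterol sensors in the endoplasmic reticulum, changed by -1.43. Srebf2, the transcription factor of the sterol genes, changed by -0.94, and Stard4, a cholesterol transporter, by -0.90. The median of the list was -0.08 and its mean -0.40, and the median was -0.05 without Control 1 and -0.02 without Control 3. The list passed camera with the preset correlation (adjusted p = 0.000101) but not with an estimated one (adjusted p = 0.191 with an estimated correlation), and passed fry (adjusted p = 0.0198).

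**Figure D1:**
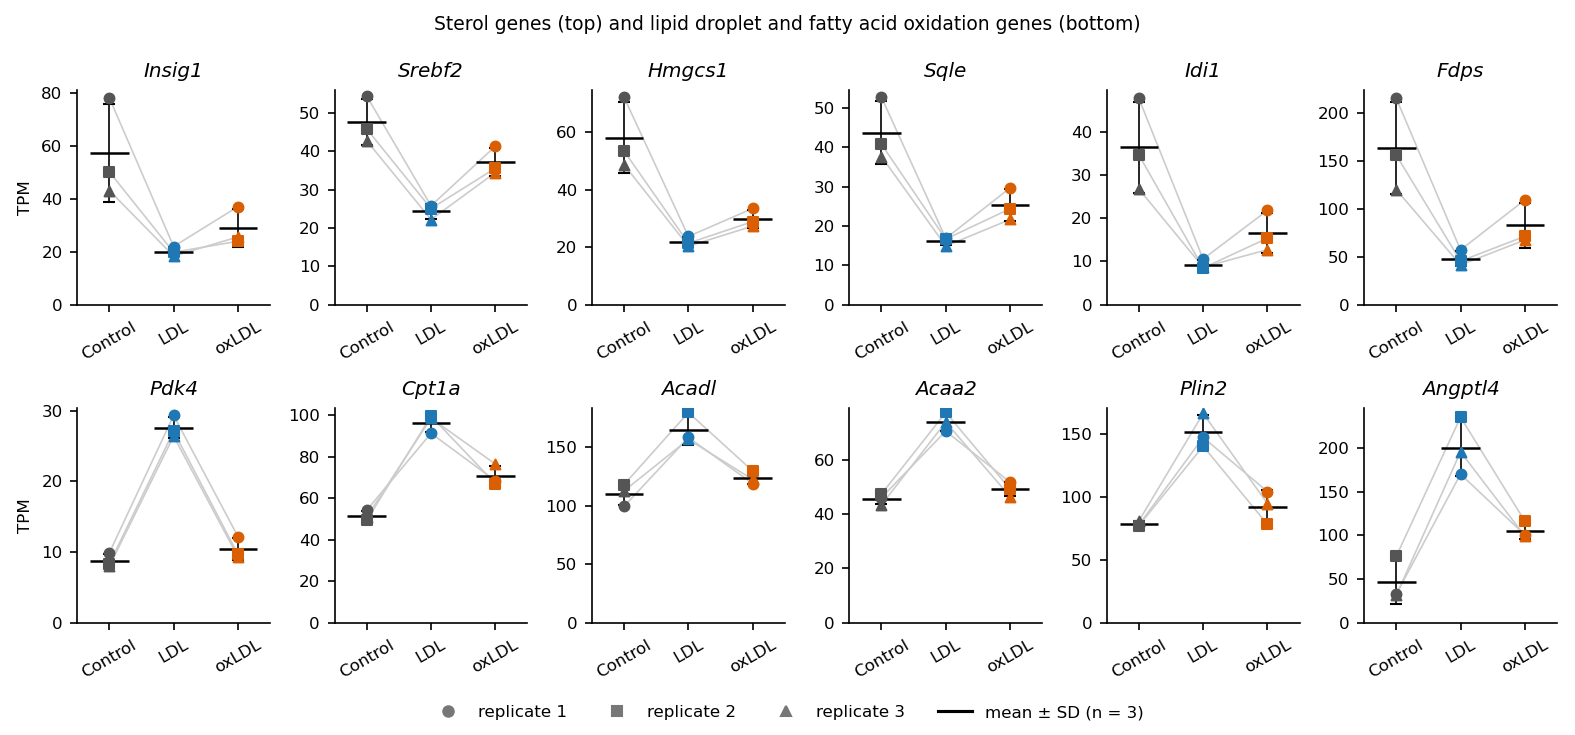
TPM per library (vertical axes, from 0) of 6 sterol genes (top) and 6 members of the PPAR target and fatty acid oxidation list (bottom) by treatment, with panels chosen after values were seen. The heading calls the bottom row lipid droplet and fatty acid oxidation genes, which leaves out that Pdk4 and Angptl4 are there as PPAR targets. Marker shapes give the replicate number, grey lines join equal numbers, and black bars are the mean ± SD of 3 libraries; Sqle averaged 43.7 TPM in Control, 16.1 TPM with LDL and 25.2 TPM with oxLDL.

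Of the 22 measured targets of PPAR (nuclear receptors activated by fatty acids) and fatty acid oxidation genes, 7 rose, 13 rose adjusted over the list alone, and 19 had a higher mean (median log2 change 0.34). Angptl4, a secreted inhibitor of lipoprotein lipase, averaged 200 ± 32.9 TPM against 46.5 ± 25.3 TPM (log2 change 2.19, adjusted p = 0.025). Pdk4 changed by 1.56. Cpt1a, which admits long-chain fatty acids to the mitochondria, averaged 96.4 ± 4.5 TPM against 51.4 ± 2.5 TPM (log2 change 0.89, adjusted p = 0.0039). Plin2, a lipid droplet coat protein, changed by 0.93, and Acaa2, a thiolase of beta-oxidation, by 0.69. Lipe, the hormone-sensitive lipase, and Ucp2, a mitochondrial carrier, rose by 1.06 and 1.3 but were not on the list. Pparg (log2 difference 0.53, adjusted p = 0.87) and Cd36, a fatty acid and oxLDL receptor (1.03, adjusted p = 0.92), did not pass. The list passed the set test with the preset correlation (adjusted p = 1.31e-18) and with an estimated one (adjusted p = 0.0366), although not when that estimate was made with the block (adjusted p = 0.368). Macrophage and leukocyte markers had a median difference of 0.25 in the same direction, which did not pass (adjusted p = 0.215, and 0.82 with an estimated correlation). With the block that marker list did pass with the preset correlation (adjusted p = 0.0338, and 0.846 with an estimated correlation).

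All 25 measured targets of NRF2, the transcription factor of the antioxidant response, had higher means with LDL than in Control (median log2 change 0.56). Over all genes tested 2 of them rose, adjusted over the list alone 21 rose, and over all genes with the block 11 rose. Hmox1, which degrades haem, averaged 356 ± 85.9 TPM against 138 ± 18.4 TPM (log2 change 1.34, adjusted p = 0.026). Nqo1, a quinone reductase, averaged 480 ± 66.8 TPM against 243 ± 55.5 TPM (log2 change 1, adjusted p = 0.037). Among members chosen after their values were seen, Txnrd1 (thioredoxin reductase), Srxn1 (sulfiredoxin) and Taldo1 (of the pentose phosphate pathway) rose only with the block, by 0.83, 1.06 and 0.67. The list passed camera with the preset correlation (adjusted p = 9.61e-25) but not with an estimated one (adjusted p = 0.169 with an estimated correlation), and passed fry (adjusted p = 0.0347).

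Among the other large rises with LDL were those of Tgm2, Rarb and Dhrs3, which have known ties to retinoic acid. Tgm2, a transglutaminase, averaged 41.2 ± 2.59 TPM against 12.5 ± 3.73 TPM (log2 change 1.68, adjusted p = 0.019). Rarb, a retinoic acid receptor, changed by 1.23 (adjusted p = 0.047), and Dhrs3, which reduces retinal, by 1.12 (adjusted p = 0.04, and 0.051 with the block). Mbd1, a protein that binds methylated DNA, averaged 77.1 ± 21.7 TPM against 29.1 ± 1.22 TPM (log2 change 1.34). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 0.81 (adjusted p = 0.024) and was the 1 of 26 measured inflammatory and NF-kB target genes that passed.

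Of the genes reported whatever their result, 5 more did not pass between LDL and Control. Abca1, a cholesterol exporter, differed by 0.28 (adjusted p = 0.92) and Runx2, a factor of bone formation, by 0.04 (adjusted p = 1). Acta2, the smooth muscle actin of myofibroblasts, averaged 589 ± 63.1 TPM with LDL and 832 ± 102 TPM in Control (log2 difference -0.50, adjusted p = 0.21). Il6 differed by 0.72 (adjusted p = 0.96) and Ccl2, a monocyte attractant, by -0.55 (adjusted p = 0.97).

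The contractile and myofibroblast list lay lower with LDL (21 genes, median -0.22, adjusted p = 0.000676, and 0.191 with an estimated correlation), with 0 of its genes passing in limma, 7 at an unadjusted p under 0.05 (6 lower and 1 higher) and 1 lower adjusted over the list alone (with the block 10 lower and 1 higher). The interferon response (23 genes, median -0.39, adjusted p = 4.06e-05) and the cell cycle (35 genes, median -0.17, adjusted p = 7.68e-06) also lay lower, with 0 genes passing in limma in either and 0 and 2 at an unadjusted p under 0.05. These calls ended when the correlation was estimated (adjusted p = 0.763 and 0.8 with an estimated correlation). Glycolysis and hypoxia genes lay higher (24 genes, median 0.23, adjusted p = 3.8e-09, and 0.393 with an estimated correlation), with 0 passing in limma, 9 at an unadjusted p under 0.05 and 4 higher adjusted over the list alone (with the block 12 higher and 1 lower). In that list Hk2, a hexokinase, had a difference of 0.50 (adjusted p = 0.098) and Aldoa, an aldolase, of 0.32 (adjusted p = 0.23). Lysosome and autophagy genes passed only with the block (27 genes, median 0.05, adjusted p = 0.065 without it and 0.0124 with it, and 0.815 with the block and an estimated correlation). The cell cycle median was -0.07 without Control 3 and -0.08 without LDL 1. The interferon median ran from -0.61, without Control 1 or without LDL 3, to -0.25 without Control 3. The median of glycolysis and hypoxia was 0.14 without LDL 2.

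The remaining 18 lists did not pass camera for LDL against Control without the block, with adjusted p between 0.065 and 0.972, though LXR targets and osteogenic genes passed the mixed test of fry (adjusted p = 0.000217 and 0.006). They covered LXR targets, scavenger receptors, the amino acid response, endoplasmic reticulum chaperones, inflammation, matrix, proteases, osteogenic genes, p53 targets, immediate early genes, valve fibroblast markers, 5 marker lists of other cell types, mitochondrially encoded genes and ribosomal proteins. The inflammatory and matrix lists had medians of -0.03 each, against means of 0.06 and 0.02 and a test direction upward. Olr1, an oxLDL receptor, had a log2 difference of 1.68 (19.1 ± 2.15 against 5.67 ± 2.56 TPM) that did not pass (adjusted p = 0.13). Srebf1 (-0.48, adjusted p = 0.071) and Scd2, a fatty acid desaturase (-1.3, adjusted p = 0.072), fell only with the block (adjusted p = 0.035 and 0.0045). Bmp4, a bone morphogenetic protein of the osteogenic list, differed by -0.54 and fell only with the block (adjusted p = 0.26 without it and 0.034 with it).

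Same-numbered libraries deviated together, and with the replicate number as a block 59 genes rose and 56 fell with LDL, 44 of them called in both fits. The count of 45 fell to 11, 16 or 28 without Control 1, 2 or 3, to 21, 4 or 6 without LDL 1, 2 or 3, and to 28 or 30 without oxLDL 1 or 2. Median-ratio scaling gave 23 rises and 12 falls, quantile normalization 22 and 12, and a fit of the 6 compared libraries alone 7 and 2. Pdk4 and Cpt1a were among the 3 genes that passed in each of the 9 fits that left out 1 library. Every other called gene lost its call in at least 1 of them. All called genes kept their direction, as they must when the groups are separated.

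The comparison of oxLDL with Control asked how VICs respond to the oxidised lipoprotein. With oxLDL the cholesterol synthesis and sterol sensing lists lay lower and the NRF2 target list higher, by camera with the preset correlation but not an estimated one (adjusted p = 0.117, 0.305 and 0.117 with an estimated correlation). Hmgcs1 averaged 29.9 ± 3.19 TPM (SD, n = 3) with oxLDL and 58.1 ± 12.4 TPM (SD, n = 3) in Control, a 1.94-fold lower level that passed only with the block (adjusted p = 0.22 without it and 0.0084 with it). Nqo1 averaged 477 ± 21.1 TPM (SD, n = 3) against 243 ± 55.5 TPM (SD, n = 3), a 1.97-fold higher level that also passed only with the block (adjusted p = 0.22 and 0.046). Without the block 2 genes rose and 0 fell in limma, while 521 genes had an unadjusted p under 0.05, or 3.86% of those tested. With the block 8 rose and 9 fell, and 1226 genes (9.08%) had an unadjusted p under 0.05.

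The 2 genes that rose were Snora61, a small nucleolar RNA, and the clone-named model AC165157.5, which was singled out after its values were seen. Snora61 was listed at 10.1, 15.8 and 49.9 TPM in the oxLDL libraries, AC165157.5 at 10.1, 23.5 and 16.4 TPM, and both at 0 in the other 6 libraries. The adjusted p was 0.033 for Snora61 and 0.00082 for AC165157.5. With the other 6 libraries at 0, only the oxLDL libraries added spread to the fits of both genes. Their p-values against Control and against LDL may therefore be too small. Snora61 lies on chromosome 4 from 132310240 to 132310369 in GRCm38, inside Snhg12 on the same strand and 130 nt long. Its call was kept in 2 of the 9 fits that left out 1 library, those without oxLDL 1 or oxLDL 3. Its adjusted p was 0.25, 0.13 or 0.18 without Control 1, 2 or 3, and 0.081, 0.11 or 0.068 without LDL 1, 2 or 3. It was 0.16 without oxLDL 2, and 0.22 with a pseudocount of 5. AC165157.5 kept its call in all 9. The count of 2 was 1 without Control 1, LDL 1, LDL 2 or oxLDL 2. With protein-coding genes alone, an alternative chosen after seeing the data, 0 genes passed in limma.

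All 20 cholesterol synthesis genes had lower means with oxLDL than in Control, with a median log2 difference of -0.69. Over all genes tested 0 of them passed in limma, 18 had an unadjusted p under 0.05, 17 fell adjusted over the list alone, and 7 fell over all genes with the block. Sqle differed by -0.77 (adjusted p = 0.42 without the block and 0.021 with it). Msmo1, Fdps, Cyp51 and Idi1 also fell only with the block, and were chosen after their values were seen. The synthesis list passed with the preset correlation (adjusted p = 1.2e-31, and 0.117 with an estimated correlation). The sterol sensing list passed in the same way (13 genes, median -0.06, adjusted p = 0.00107, and 0.305 with an estimated correlation), with 0 of its genes passing in limma, 5 at an unadjusted p under 0.05, 5 lower adjusted over the list alone, and 1 with the block. Its median was -0.30 without oxLDL 3, -0.13 without Control 2 and -0.03 without oxLDL 1.

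All 25 NRF2 targets had higher means with oxLDL (median log2 difference 0.54). Over all genes 0 passed in limma, 17 had an unadjusted p under 0.05, 17 rose adjusted over the list alone, and 3 rose with the block, namely Nqo1, Pgd and Txnrd1, the last chosen after its values were seen. Pgd, of the pentose phosphate pathway, averaged 279 ± 4.93 TPM against 191 ± 6.83 TPM (log2 difference 0.54, adjusted p = 0.073 without the block and 0.0091 with it). Hmox1 averaged 270 ± 50.9 TPM against 138 ± 18.4 TPM and did not pass (log2 difference 0.95, adjusted p = 0.46). The list passed camera with the preset correlation (adjusted p = 2.09e-29) but not with an estimated one (adjusted p = 0.117 with an estimated correlation).

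Ptgs2 averaged 94.2 ± 11.2 TPM against 52 ± 3.84 TPM with oxLDL and rose by 0.84 only with the block (adjusted p = 0.091 without it and 0.0035 with it). Alas1, the entry enzyme of haem synthesis, rose by 0.64 with the block (adjusted p = 0.0084). Ogn, the matrix proteoglycan osteoglycin, averaged 41 ± 6.97 TPM against 80.3 ± 13.9 TPM and fell with the block (log2 change -0.95, adjusted p = 0.0032). Alas1 and Ogn were chosen after their values were seen. The inflammatory list lay higher (26 genes, median 0.23, adjusted p = 0.000622, and 0.677 with an estimated correlation), with Ptgs2 the 1 gene that rose adjusted over the list alone (2 with the block). That call ended without Control 1, Control 3 or oxLDL 2, where the medians were 0.09, 0.19 and 0.09, and the median was 0.53 without Control 2 and 0.40 without oxLDL 1. Il11, a cytokine of fibroblasts, differed by 0.61 (adjusted p = 1), Il6 by 0.70 (adjusted p = 1) and Ccl2 by 0.19 (adjusted p = 1).

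Genes of the p53 list lay higher with oxLDL (18 genes, median 0.18, adjusted p = 1.37e-06, and 0.1 with an estimated correlation), with 0 passing in limma, 5 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (6 with the block). By the PValue of fry that list passed only without the block (adjusted p = 0.0348, and 0.0582 with it), and the cholesterol synthesis list only with it (adjusted p = 0.064 without it and 0.0154 with it). Cdkn1a, a cell cycle inhibitor, averaged 202 ± 0.652 TPM against 160 ± 7.17 TPM (log2 difference 0.33, adjusted p = 0.42). Fatty acid oxidation and PPAR target genes lay higher by a median of 0.11 (adjusted p = 0.000193, and 0.288 with an estimated correlation), with 0 passing in limma, 3 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone. Without oxLDL 1 that call ended (median 0.08, adjusted p = 0.14). Angptl4 differed by 1.28 (adjusted p = 0.64), Cpt1a by 0.45 (adjusted p = 0.23) and Plin2 by 0.22 (adjusted p = 1). Interferon response genes lay lower (23 genes, median -0.46, adjusted p = 2.86e-07, and 0.677 with an estimated correlation), but not past the threshold without oxLDL 1 (median -0.13, adjusted p = 0.059), and by -0.97 without oxLDL 3. In limma 0 of them passed and 1 had an unadjusted p under 0.05.

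The cell cycle (median -0.10, adjusted p = 0.0182), glycolysis and hypoxia (0.08, adjusted p = 0.0182), chaperone (-0.06, adjusted p = 0.0487) and immediate early (0.06, adjusted p = 0.0487) lists also passed with the preset correlation, with 0 genes passing in limma in each and 1, 2, 0 and 1 at an unadjusted p under 0.05. Their adjusted p was 0.917, 0.886, 0.886 and 0.677 with an estimated correlation. The cell cycle call ended without Control 2 or 3 or oxLDL 1 or 3 (medians -0.10, 0.01, -0.01 and -0.07), and its median was -0.20 without Control 1 and -0.22 without oxLDL 2. The glycolysis call ended without Control 1 or 3 or oxLDL 1 or 2 (0.04, 0.03, 0.11 and 0.08), and its median was 0.18 without Control 2 and 0.05 without oxLDL 3. The chaperone call ended without Control 1 or 2, LDL 1, or oxLDL 1 or 3 (-0.06, -0.03, -0.06, -0.07 and -0.06), with -0.13 without Control 3. The immediate early call ended without Control 1 or 2, LDL 3, or oxLDL 1 or 2 (0.06, 0.01, 0.06, 0.10 and 0.04), with 0.12 without Control 3 and 0.09 without oxLDL 3. Endothelial markers (16 genes, median -0.15) and mitochondrially encoded genes (13 genes, median -0.11) passed only with the block (adjusted p = 0.0068 and 0.02 with the preset correlation, both 0.611 with an estimated correlation). The mitochondrial list had a mean difference of -0.257. Its mean log2(TPM + 1) was 9.289, 10.486 and 10.739 in oxLDL 1, 2 and 3, against 9.766, 10.667 and 10.852 in Control 1, 2 and 3. The largest gap was in number 1, where its member mt-Co2 was listed at 0 with oxLDL. The other 14 lists did not pass camera, with adjusted p between 0.0662 and 0.998. Among them median, mean and test differed in sign, or the mean was 0, for osteogenic genes (0.01, 0 and downward), macrophage markers (-0.02, 0 and downward), melanocyte markers (-0.06, 0.04 and upward) and matrix genes (0.01, -0.01 and upward). Abca1, Cd36, Pparg, Acta2 and Runx2 had differences of 0.34, 0.34, -0.12, -0.18 and 0.17 (all with an adjusted p of 1), and did not pass with the block either.

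The comparison of oxLDL with LDL asked what oxidation of the lipoprotein changed. Tgm2, a transglutaminase, was lower with oxLDL than with LDL, at 11.4 ± 2.52 TPM (SD, n = 3) against 41.2 ± 2.59 TPM (SD, n = 3), a 3.61-fold difference (log2 -1.78, 95% CI -2.24 to -1.32, adjusted p = 0.025). Of the 22 PPAR target and fatty acid oxidation genes 3 were lower with oxLDL, among them Pdk4 at 10.4 ± 1.57 TPM (SD, n = 3) against 27.6 ± 1.53 TPM (SD, n = 3) (log2 -1.34, adjusted p = 0.0059). In all 5 genes were higher and 9 lower with oxLDL, and 528 genes (3.91%) had an unadjusted p under 0.05, or 1148 (8.51%) with the block. With the block 16 were higher and 19 lower, and all 14 genes called without it were among them.

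Of the 22 fatty acid oxidation and PPAR target genes, 3 were lower with oxLDL than with LDL, 9 were lower adjusted over the list alone, 5 with the block, and 20 had a lower mean (median log2 difference -0.26). Among them, besides Pdk4, was Acaa2 (49.2 ± 2.65 against 74 ± 3.45 TPM, log2 -0.58). Plin2 was lower only with the block (log2 -0.71, adjusted p = 0.072 without it and 0.029 with it), while Pparg (-0.65, adjusted p = 1) and Cd36 (-0.69, adjusted p = 1) did not pass. The list passed with the preset correlation (adjusted p = 3.08e-18) and with an estimated one (adjusted p = 0.036), though not when the estimate was made with the block (adjusted p = 0.399). Its median was -0.14 without oxLDL 2, with the call kept. All 18 macrophage and leukocyte markers also had lower means with oxLDL (median -0.26), which passed only with the block (adjusted p = 0.127 without it and 0.00744 with it, and 0.893 with the block and an estimated correlation). The mean log2(TPM + 1) of these markers was 3.454, 1.87 and 4.357 in oxLDL 1, 2 and 3. It was 4.025, 2.738 and 3.765 in LDL 1, 2 and 3, so the libraries numbered 3 went the other way. Csf1r, the macrophage growth factor receptor, differed by -0.24 (adjusted p = 1).

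Cholesterol synthesis genes lay higher with oxLDL than with LDL (20 genes, median log2 difference 0.42, adjusted p = 1.06e-15, and 0.318 with an estimated correlation). Over all genes 0 passed in limma, 10 had an unadjusted p under 0.05, 1 was higher adjusted over the list alone (13 with the block), and 5 over all genes with the block, with Fdps, chosen after its values were seen, at 82.5 ± 23.1 against 47.9 ± 8.12 TPM (log2 0.75, adjusted p = 0.83 without the block and 0.027 with it). The difference from Control was closer to 0 with oxLDL than with LDL in 19 of the 20 genes, and the median ratio of both changes was 0.597. The sterol sensing list, where 1 gene passed (2 with the block) and 3 were higher adjusted over the list alone, lay higher by a median of 0.05 (adjusted p = 0.00805, and 0.412 with an estimated correlation). That call ended without oxLDL 3 (median -0.02, adjusted p = 0.057), and the median was 0.07 without LDL 1, 0.01 without LDL 2 and 0.14 without oxLDL 2. NRF2 targets had a median difference of -0.03 between oxLDL and LDL (adjusted p = 0.599), with 0 genes passing in limma and 1 at an unadjusted p under 0.05, and Hmox1 differed by -0.39 (95% CI -0.82 to 0.03, adjusted p = 1).

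**Figure D2:**
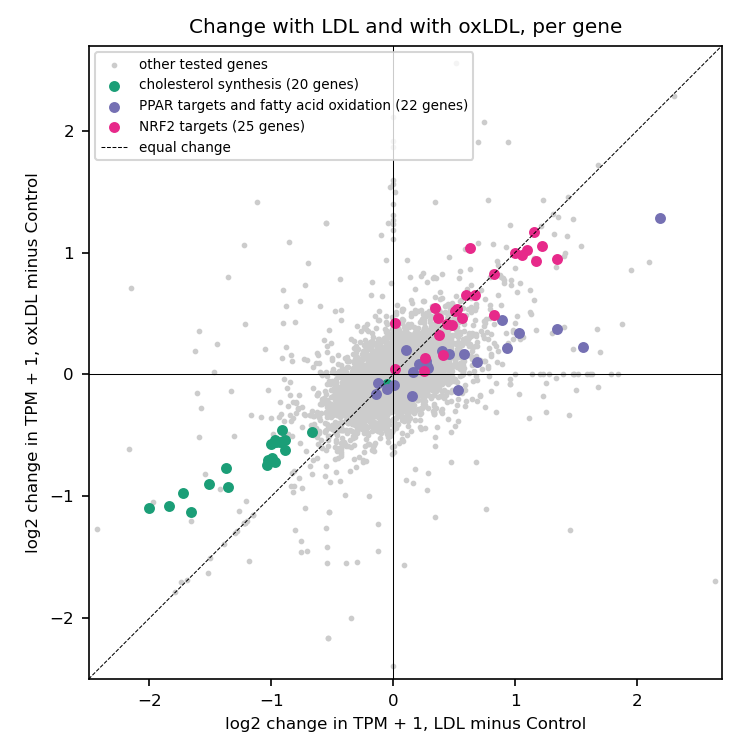
Log2 change in TPM + 1 against Control with LDL (horizontal axis) and oxLDL (vertical axis), one point per tested gene, with 17 genes outside the plotted range. Cholesterol synthesis genes (green) lie nearer to 0 on the oxLDL axis (medians -1 and -0.69), as do PPAR and fatty acid oxidation genes (purple, 0.34 and 0.11), and NRF2 targets (pink, 0.56 and 0.54) lie near the dashed line of equal change; both axes share the Control libraries.

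Genes outside these lists that were lower with oxLDL than with LDL included, besides Tgm2, Dhrs3 (19.6 ± 4.06 against 55.6 ± 6.41 TPM, log2 -1.47, adjusted p = 0.025) and Mbd1 (log2 -1.36, adjusted p = 0.029). Stbd1, which tethers glycogen to membranes, averaged 24.9 ± 1.64 against 46.9 ± 3.44 TPM (log2 -0.89, adjusted p = 0.0059). Etfbkmt, a mitochondrial lysine methyltransferase, differed by -0.91 and Atp1b1, a subunit of the sodium pump, by -0.67. Gng2, a G protein subunit, was higher with oxLDL (15.8 ± 1.14 against 8.31 ± 0.977 TPM, log2 0.86), as was Rab3ip, an exchange factor for Rab GTPases (0.51). Snora61 and AC165157.5 (the latter chosen after its values were seen) were also higher (adjusted p = 0.016 and 0.00082), both being listed at 0 in the LDL libraries.

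The inflammatory list lay higher with oxLDL than with LDL (26 genes, median 0.15, adjusted p = 0.0106, and 0.971 with an estimated correlation), with 0 genes passing in limma and 1 at an unadjusted p under 0.05. Ccl20, a chemokine, averaged 6.03 ± 3.31 against 1.44 ± 0.608 TPM and passed only with the block (log2 1.45, adjusted p = 0.8 without it and 0.04 with it). Ccl2 averaged 797 ± 311 against 478 ± 179 TPM and passed only with the block (log2 0.73, adjusted p = 1 without it and 0.044 with it), and Il6 did not pass (-0.03, adjusted p = 1). The list call ended without LDL 1, LDL 3 or oxLDL 2, with medians of 0.02, 0.19 and 0.05, and the median was 0.34 without LDL 2, 0.30 without oxLDL 1 and 0.23 without oxLDL 3.

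Contractile genes lay higher with oxLDL than with LDL (21 genes, median 0.15, adjusted p = 4.78e-05, and 0.232 with an estimated correlation) and glycolysis and hypoxia genes lower (24 genes, median -0.12, adjusted p = 5.47e-06, and 0.586 with an estimated correlation), with 0 genes passing in limma in either and 4 and 3 at an unadjusted p under 0.05. The contractile median was 0.09 without oxLDL 3, and that of glycolysis and hypoxia was -0.07 without LDL 2 and -0.20 without LDL 1. Acta2 differed by 0.32 (adjusted p = 0.93), Abca1 by 0.06 and Runx2 by 0.13 (both with an adjusted p of 1). The immediate early (median 0.15), cell cycle (0.08), p53 (0.09) and lysosome (-0.05) lists passed with the preset correlation (adjusted p = 0.00127, 0.0105, 0.0105 and 0.0476). Their adjusted p was 0.396, 0.971, 0.318 and 0.971 with an estimated correlation, and 0 genes passed in limma in any of them, with 4, 0, 0 and 1 at an unadjusted p under 0.05. The immediate early call ended without LDL 3 or oxLDL 2 (medians 0.13 and 0.07), and the cell cycle call without LDL 1 or oxLDL 2 (-0.02 and -0.04), with 0.15 without LDL 2 and 0.16 without oxLDL 1. The p53 call ended without oxLDL 1 or 2 (both 0.08), with 0.04 without LDL 1. The lysosome call ended without Control 2 or 3 (both -0.05), LDL 1 (0.03), or oxLDL 2 or 3 (0.05 and -0.09), with -0.13 and -0.09 without LDL 2 or 3 and -0.15 without oxLDL 1. Melanocyte and glia markers passed only with the block (7 genes, median -0.17, adjusted p = 0.0311, and 0.578 with an estimated correlation). The other 14 lists besides NRF2 did not pass camera, with adjusted p between 0.145 and 0.958. Median, mean and test differed in sign for LXR targets (-0.01, 0.05 and upward), the amino acid response (0.01, -0.01 and upward), chaperones (0, 0 and downward), matrix (0.02, -0.03 and upward) and valve markers (0.01, -0.03 and downward).

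The count of 14 genes fell to 6 or 3 without Control 1 or 2, to 7, 4 or 4 without LDL 1, 2 or 3, and to 6, 1 or 8 without oxLDL 1, 2 or 3. Only AC165157.5 passed in each of the 9 fits that left out 1 library, while Pdk4 and Stbd1 missed only without oxLDL 2 (adjusted p = 0.056 for both). Sample quality weights gave 5 genes higher and 18 lower, and a fit of the 6 compared libraries alone 1 and 5.

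**Figure D3:**
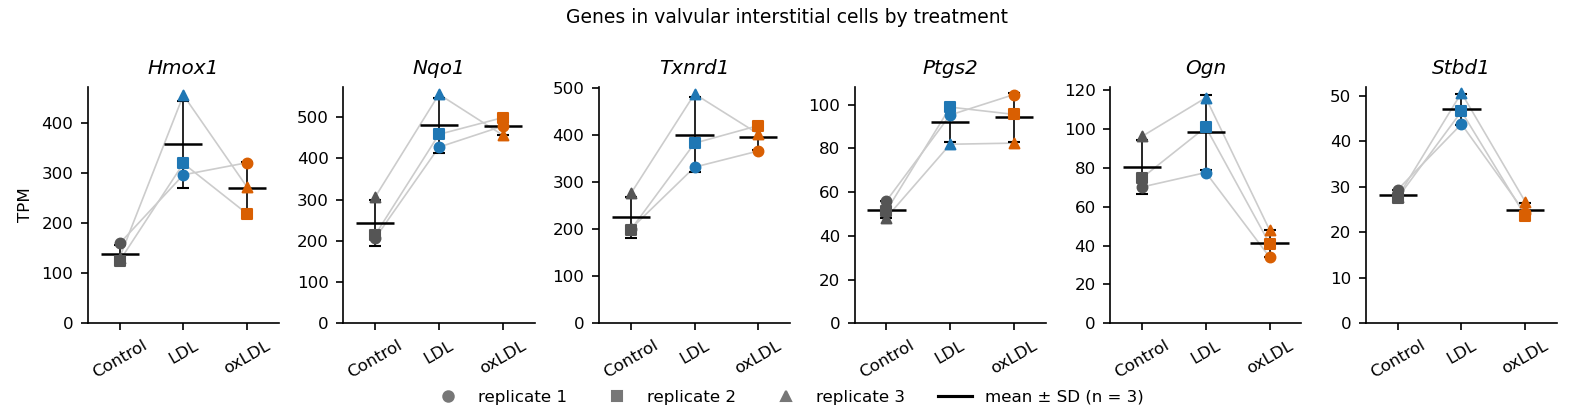
TPM per library (vertical axes, from 0) of Hmox1, Nqo1, Txnrd1, Ptgs2, Ogn and Stbd1, chosen after their values were seen, by treatment, with replicate numbers as marker shapes, grey lines joining equal numbers and black bars for the mean ± SD of 3 libraries. Nqo1 averaged 243 TPM in Control, 480 TPM with LDL and 477 TPM with oxLDL, whereas Stbd1 averaged 28.2, 46.9 and 24.9 TPM.

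The changes with LDL and with oxLDL were compared across genes, with the caution that both used the same Control libraries and that genes are not independent replicates. The log2 changes correlated with r = 0.545, against a mean of 0.496 and a highest value of 0.569 over 100 simulations of unchanged groups against shared controls. Their covariance was 0.031 against a simulated mean of 0.0228 and highest of 0.0301, or 0.0138 and 0.017 in simulations with the block. The share of genes with the same sign was 70.5% against a simulated mean of 66.7% and highest of 68.2%. The simulated noise was drawn independently for each gene, so the simulated ranges may be too narrow. Without the block it counted shifts by replicate number as independent noise, although same-numbered libraries deviated together. That can raise the simulated covariance, whose mean was 0.0228 without the block and 0.0138 with it. Values above the simulated ranges do not by themselves show a shared response. Without the block 0 genes were called in both comparisons in limma. With the block 6 were higher in both (Ptgs2, Alas1, Nqo1, Pgd, Txnrd1 and Gstp1, a glutathione transferase) and 8 lower in both (among them Idi1, Fdps, Msmo1, Cyp51, Sqle and Hmgcs1), all named here because of their values. The simulations, which hold the shared controls but no changed genes, gave means of 0 and 0.01 such genes. Independent lists, which leave out the shared controls, would share 0.035 and 0.0373. Neither baseline joins changed genes with shared controls, so the excess over either does not by itself measure a shared effect. Part of the excess may come from the shared controls, since the 3 Control libraries cannot be split into parts that each keep 2.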

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

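The tests of macrophage markers and of library scaling, and the counting criterion applied to short genes, were chosen only after their results were seen, and the other tests here were written before.

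Stbd1 differed between the responses to the lipoproteins, and the difference itself was tested (log2 -0.89 for oxLDL minus LDL, limma adjusted p = 0.0059). Its values were 29.33, 27.55 and 27.7 TPM in Control, 43.74, 46.51 and 50.57 TPM with LDL, and 24.23, 23.63 and 26.73 TPM with oxLDL. Stbd1 was picked because it passed this test with all LDL values above all Control values and all Control values above all oxLDL values. Being lower with oxLDL than with LDL in 3 of 3 pairs of equal replicate number follows from that and adds no support. Its difference between oxLDL and Control was -0.18 (adjusted p = 1).

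The fatty acid oxidation and PPAR target genes lay higher with LDL than with oxLDL (camera adjusted p = 3.08e-18, and 0.036 with an estimated correlation), and 3 other explanations were examined. A difference in scaling would move all genes alike. All other tested genes had a median of 0.001 against -0.26 for the list, so no common shift was seen. Camera compares a list with the other genes, so a common shift could not have made the call, and this check adds no support. Median-ratio factors hardly differed between these groups, so refitting with them tested nothing. Of 8 adipocyte markers, 0 reached a mean of 1 TPM in the LDL libraries, the highest being Car3 at 0.343 TPM, which argues against adipocytes among the cells. With each library's mean macrophage marker level as a covariate the median was -0.23 against -0.26 without it. The replicate number accounted for 76.4% of the variation of these markers and the treatment for 3.45%. The adjustment therefore rests mainly on differences between replicate numbers, which this fit left out, and cannot settle whether macrophages contributed. It replaced a test that rested on replicate pair 3, where the markers were lower with LDL (-0.45) and the list higher (0.23), because a single pair excludes nothing. The lipoprotein itself may underlie the difference, a hypothesis that stays open because no other treatment tested it.

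Snora61 and AC165157.5 were listed above 0 in the 3 oxLDL libraries and at 0 in the other 6. The gene that spans Snora61, Snhg12, changed by 0.09 between oxLDL and Control and by 0.01 between oxLDL and LDL, which argues against reads spilling over from a host gene that rose. Unstable TPM of very short genes stays open: 13 genes were at 5 TPM or more in exactly 3 libraries and at 0 in the other 6, and 11 of the 12 with a length were under 300 nt. The oxLDL libraries held 2 of these genes and any other 3 libraries at most 1, over 84 ways to pick 3. That had met the bound set beforehand, but 2 against 1 lies within counting spread, so the bound was too weak and was replaced after the result was seen, and a response to oxLDL may or may not be present.

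Other splits of the 6 libraries of each comparison were too few (10) for a share under 0.05, and 1 split, the real one, gave a count as large in each case. For LDL against Control the real count was 45 (115 with the block) and the highest other 1 (1 with the block). For oxLDL against Control these were 2 and 1 (17 and 1 with the block), and for oxLDL against LDL 14 and 2 (35 and 2 with the block). Among splits that part all 3 pairs, the highest others were 0, 1 and 2, and 0, 0 and 2 with the block.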

How the results depend on the processing

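Leaving out the libraries numbered 1, which stood apart, and testing only protein-coding genes were tests chosen after seeing the data. Of 1394 alternative values of the 61 called gene results, 813 kept the call and 581 lost it. All 1394 kept their direction, but the groups of every called gene were separated. Leaving out a library or changing the pseudocount, filter, prior, sample weights or block could not reverse such a gene, so this adds little. The median log2 change of all genes stayed within 0.027 of 0 in every setting. Causes were not tested, except that fewer libraries give fewer degrees of freedom. The unknown depth keeps counting error from being separated from other spread.

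Counts of genes called are given for LDL against Control, oxLDL against Control and oxLDL against LDL, with 45, 2 and 14 as reported. The replicate block gave 115, 17 and 35, no filter on low values 19, 10 and 8, and only the compared groups in the fit 9, 1 and 6. A pseudocount of 5 gave 1 for oxLDL against Control, and a prior variance the same for all genes gave 1 there and 8 for oxLDL against LDL. Sample quality weights gave 23 genes for oxLDL against LDL and 13 lists for LDL against Control. Without the libraries numbered 1 the counts were 11, 2 and 7, and with the block 9, 0 and 3. Protein-coding genes alone gave 0 for oxLDL against Control in limma, where all genes had 521 at an unadjusted p under 0.05. Over all genes and with camera the block changed no call other than those printed and the genes behind its counts.

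Lists called fell from 8, 11 and 10 to 1, 0 and 1 with a correlation estimated per list, and to 4, 1 and 1 with fry. The mixed test of fry called 8, 5 and 2 lists, and 17, 9 and 7 with the block.

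Leaving out 1 library at a time gave 4 to 37, 1 to 3 and 1 to 10 genes. Lists called ran from 8 to 13 for LDL against Control and from 7 to 14 for oxLDL against Control. A measure of a shared response to LDL and oxLDL, the correlation of 0.545, lay within simulations without effects (mean 0.496, highest 0.569) and so shows none by itself. The covariance (0.031 against a highest of 0.0301) and the share of equal signs (70.5% against 68.2%) lay above these simulations, which drew genes independently. The correlation ran from 0.423 without oxLDL 3 to 0.657 without Control 1, and no simulations were made for these smaller sets. The cell cycle median ran from -0.22 to 0.01 for oxLDL against Control and from -0.04 to 0.16 for oxLDL against LDL, and the lysosome median from -0.15 to 0.05 for oxLDL against LDL, so each changed sign.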

Other observations

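The test of library scaling was chosen only after the result was seen, that of other retinoic acid receptor targets was written before, and the genes and patterns below were chosen after their values were seen.

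Elovl6, Pcyt2, Acsl3 and Mid1ip1, of fatty acid and phospholipid synthesis, fell with LDL, but no list of such genes was tested. Elovl6, a fatty acid elongase, changed by -0.88 (limma adjusted p = 0.034), Pcyt2, of phosphatidylethanolamine synthesis, by -0.87 (0.02), Acsl3, an acyl-CoA synthetase, by -0.67 (0.043) and Mid1ip1, a regulator of acetyl-CoA carboxylase, by -0.60 (0.01). Fads2 and Fads1, fatty acid desaturases, and Fasn, the fatty acid synthase, fell only with the block, by 0.98, 0.61 and 0.61 on the log2 scale (adjusted p = 0.012, 0.017 and 0.019). Mid1ip1 kept the call in 7 of the 9 fits that left out 1 library, Pcyt2 in 4, and Elovl6 and Acsl3 in 0.

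Blvrb, Slc48a1 and Alas1, of haem handling, rose with LDL, but no list of such genes was tested. Blvrb, a biliverdin reductase, averaged 179 ± 35.8 against 94.4 ± 7.19 TPM (SD, n = 3; log2 0.90, limma adjusted p = 0.026), Slc48a1, a haem transporter, 125 ± 15.6 against 77.7 ± 3.25 TPM (log2 0.68, adjusted p = 0.022), and Alas1 169 ± 17 against 106 ± 9.87 TPM (log2 0.67, adjusted p = 0.025). Ftl1, the ferritin light chain, and Slc40a1, the iron exporter, rose only with the block (log2 0.44 and 0.99, adjusted p = 0.022 and 0.03). Blvrb and Alas1 kept the call in 2 of the 9 fits that left out 1 library and Slc48a1 in 4.

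The replicate number accounted for much of the variation between libraries. The first principal component (26.9% of variance) placed the libraries numbered 1 at -21.8 to -26.2 and the others at 7.2 to 16.1. The number accounted for 94.1% of the variation of the endothelial marker list, 90.9% of the mitochondrially encoded genes and 76.4% of the macrophage markers, while the treatment accounted for 88.1% of cholesterol synthesis and 88.8% of the PPAR list. Over the 27 lists the share of the number ran from 3.73% (contractile genes) to 94.1%. That of the treatment ran from 0.794% (matrix genes) to 88.8%, and some share falls to either by chance. The transcript mt-Co2 was listed at 19.3, 18.96 and 0 TPM in the libraries numbered 1 (Control, LDL and oxLDL), and at 288.97 to 651.32 TPM in the others.

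Rarb, Dhrs3 and Tgm2, known retinoic acid receptor targets, were higher with LDL than with Control, and Dhrs3 and Tgm2 were lower with oxLDL than with LDL (Rarb only with the block, adjusted p = 0.051 without it). All other tested genes had a median of 0.001 for oxLDL minus LDL, against -1.47 for these 3. No shift common to all genes, as a difference in scaling would give, was therefore seen. These 3 genes were picked after their large differences were seen, so the contrast adds no support. A wider retinoic acid receptor response to LDL may be a candidate explanation: 10 other targets had a median log2 difference of 0.18, at percentile 99.9 of 10000 random lists matched on expression (-0.1 to 0.09), with 8 of 10 higher, 0 passing in limma and 2 at an unadjusted p under 0.05. The largest difference was that of Cyp26b1, which degrades retinoic acid (1.44). Random lists treat genes as independent and ignore the spread between samples, so the percentile overstates the evidence. For these 10 targets the unadjusted p was 0.0035 by camera with the preset correlation, 0.032 with an estimated correlation and 0.03 by fry. For oxLDL against Control the median was -0.01, and the retinoid content of the lipoproteins and medium is not given in the sources used here.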
